A study of Mus musculus with 15 samples.

How the data were processed

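PolyA RNA was sequenced from 15 libraries of mouse embryonic fibroblasts. Per the labels' protocols, the cells were infected with lentiviruses that express Neurog1 or Neurog3 (labelled Ngn1 and Ngn3) under doxycycline control, and were collected after 24 h (day 1) or after 13 days. The same protocols replace the fibroblast medium by a neuronal medium on day 2. The 5 groups of 3 libraries are the controls, Neurog1 at day 1, Neurog3 at day 1, Neurog1 at day 13 and Neurog3 at day 13. The controls are labelled only as control, so their virus, medium and time in culture are not given in the sources used here. Nothing states that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, part of which may be technical.

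The deposited values are raw counts of reads per gene, 1 column per library, keyed by Ensembl gene ID. Per the submitters' processing notes, the authors made these counts with CASAVA, HISAT2 and featureCounts on mm10. The notes give no versions, no annotation release and no strand setting. Reads of a gene and of an antisense or overlapping neighbour therefore could not be told apart, and reads of the viral Neurog1 and Neurog3 transcripts could not be told apart from those of the endogenous genes. Genes with near-identical copies, such as Lyz2, Psg22, Lce1h, the actins Acta1, Acta2 and Actc1, and glycolytic enzymes with many pseudogenes, carry the same uncertainty.

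Gene symbols and coordinates were taken from GENCODE M21 (mm10), which named 42462 of the 43432 IDs in the deposited table. The other 970 IDs held 0.142% of all counts, and 113 of them were among the genes tested. In 14485 genes every library had 0 counts. Symbols follow that release, so Prrxl1 and Ddx58 stand for list members now called Drgx and Rigi.

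The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the raw counts, with 1 mean per group, all 15 libraries in 1 fit, TMM factors and edgeR's expression filter, which left 16872 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and "rose", "fell" and "changed" are used of called genes only. The number of called genes with at least a 2-fold change is given beside each count. There were 8 comparisons: each factor against the controls at each day, day 13 against day 1 for each factor, and the factors against each other at each day. An interaction contrast asked whether the change from day 1 to day 13 differed between the factors. Log2 fold changes are edgeR's fitted values (prior count 0.125) with their standard errors. Levels are CPM on TMM-scaled library sizes, computed here as means of 3 libraries, with ± giving the SD.

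Where the lower group of a comparison had 0 counts in all its libraries, the fold is a lower bound computed against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only.

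A set of 29 gene lists (526 distinct genes, 0 of them missing from the table) was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of 1 comparison. The counts of members called are given over all genes tested and adjusted over the list alone. The size given for a list is the number of its members that passed the expression filter. Listed genes with few or no reads are therefore not in it. Median log2 fold changes are given a second time, with genes at their bounds, where that changes them. The lists cover the proneural cascade, neuronal cytoskeleton and RNA binding, synapse and vesicle release, neuronal ion channels and receptors, glutamatergic, GABAergic, cholinergic and motor, peripheral sensory and monoaminergic neurons, neural progenitors, the Notch pathway, and pancreatic and enteric endocrine cells. They also cover fibroblast identity and matrix, contractile and myofibroblast genes, skeletal muscle, the cell cycle, cell cycle inhibitors and p53 targets, cholesterol synthesis, interferon response, inflammatory cytokines and proteases, stress and immediate early genes and glycolysis. The rest are marker lists for macrophages, endothelial cells, epithelial cells, adipocytes, cartilage and bone, astrocytes and oligodendrocytes, and neural crest and Schwann cells. Some genes are in more than 1 list.

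The lists, the tests, the thresholds, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule names a fixed set of anchor genes, the 6 highest and 6 lowest log2 fold changes per comparison among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, and the most abundant called and uncalled members of each list. Predicted gene models were left out of the top 6, and not every gene the rule names is printed. Other genes named were chosen after their values were seen, which is said where they appear.

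The letters a, b and c of the replicates were compared across groups, since the labels do not say whether they mark pairs. Residuals from the group means were correlated across genes for libraries of the same letter. Between the factors at day 1 the correlations were 0.454, 0.539 and 0.325 for letters a, b and c, and at day 13 they were 0.58, 0.521 and 0.575. In each of these 2 comparisons 6 of 6 libraries correlated best with the library of their own letter. The same held for Neurog1 at day 1 against the controls and for day 13 against day 1 with Neurog3, and for 5 of 6 libraries of Neurog3 at day 1 against the controls. For day 13 against day 1 with Neurog1 the count was 2 of 6. For day 13 against the controls it was 0 of 6 with each factor, and all these correlations were negative. In each of the 6 comparisons that are not between the factors, the lowest of the 3 correlations was at most 0.0648. A pairing was accepted only where all 3 correlations were over 0.1, so the letters were treated as pairs only between the factors of the same day. The pairing thus comes from the data and not from a label. A fit of the 12 libraries with a factor, with a separate term for the letter at each day, is called the fit with a replicate block within day. It was chosen after seeing the data.

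The alternatives for the gene counts were DESeq2-style size factors in edgeR, library totals only, no low-count filter, a minimum mean CPM of 1, DESeq2's Wald test (DESeq2 1.42.0), a fit of only the groups compared, a 2-fold minimum, an adjusted p under 0.01, the letter as a block over all libraries, and leaving out each library in turn. For the lists they were an estimated correlation, limma's fry, the letter block and library totals. Chosen after seeing the data were edgeR's robust option, leaving out 1 letter from every group, and the replicate block within day.

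The gene and list tests of 3 of the 8 comparisons were run on simulated data drawn for the 16872 genes with 100 genes changed 2-fold and 100 changed 4-fold. The other comparisons and the interaction were not simulated in this way. For Neurog1 at day 1 against the controls the main test recovered 21% of the 2-fold and 85% of the 4-fold changes. It recovered 34% and 91% for the factors at day 1, and 25% and 77% for the factors at day 13. With the replicate block within day, on libraries simulated in pairs, the shares were 80% and 98% at day 1 and 82% and 98% at day 13. That fit made 20 false calls among 200 at day 13 and 4 among 182 at day 1. On the same simulated pairs the fit without the block recovered 11% and 84% at day 1, and 14% and 63% at day 13. A simulated list of 30 genes raised 2-fold was recovered, with 0 other lists called. This does not test false calls in lists whose genes are correlated. In the real data, the list calls over the 8 comparisons and the interaction fell from 89 to 5 with an estimated correlation. The simulation therefore cannot tell how many of the 89 calls are false.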

Results

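PolyA RNA from 15 mouse embryonic fibroblast libraries was counted per gene in 5 groups of 3. The groups were control cells, cells expressing the proneural factor Neurog1 at day 1 or day 13, and cells expressing its relative Neurog3 at day 1 or day 13. Neurog1 and Neurog3 are basic helix-loop-helix factors: Neurog1 acts in sensory and cranial neurogenesis, and Neurog3 is best known from endocrine cells of the pancreas and gut. Libraries held 16778296 to 17859844 counts in the controls, 16736544 to 17645853 and 16179235 to 17361026 at day 1 (Neurog1, Neurog3), and 16376231 to 17470737 and 14869015 to 17244012 at day 13. The number of genes with at least 1 count was 20429 ± 289 in the controls, 20639 ± 118 and 20667 ± 666 at day 1, and 22053 ± 816 and 21828 ± 693 at day 13 (SD, n = 3).

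The delivered factor was found in the groups labelled with it. Neurog1 (ENSMUSG00000048904, chromosome 13, 56250478 to 56252163, minus strand, mm10) had 0 counts in the 3 controls. It had 31250, 65277 and 16252 counts in replicates a, b and c of Neurog1 at day 1, and 22766, 61015 and 80443 at day 13. These are 2327 ± 1399.8 and 2829.8 ± 1422 CPM, at least 37656-fold and at least 45406-fold above the controls. Neurog3 (chromosome 10, 62133090 to 62134763, plus strand) had 1 count in the controls, 20393, 52069 and 20429 counts in Neurog3 at day 1, and 22349, 98008 and 90297 at day 13. These are 1909 ± 963 and 3860.1 ± 2269 CPM. The ratio to the controls was 92568-fold with a 95% counting interval of 16614 to 3656296 at day 1 and 183089-fold with a 95% counting interval of 32861 to 7231680.5 at day 13. Each factor had at most 13 counts in any library labelled with the other factor. Neither level was called different between day 13 and day 1 (log2 fold change 0.28 ± 0.56, adjusted p = 0.683 for Neurog1; 1.02 ± 0.57, adjusted p = 0.14 for Neurog3). Neurog2, the third member of the family, had at most 7 counts in any of the 15 libraries.

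Libraries separated by day. The first principal component held 70.81% of the variance and parted the day-13 libraries from the others. The second held 11.36% and parted the controls from the day-1 libraries. Pearson's r between libraries, across genes, was 0.957 to 0.984 within groups and 0.951 to 0.987 between the factors of the same day. It was 0.92 to 0.953 between day 1 and the controls, and 0.759 to 0.843 between day 13 and the controls. Mitochondrial transcripts took 3.51% ± 0.425 of counts in the controls and 2.22% ± 0.53 and 2.33% ± 0.802 at day 13 (Neurog1, Neurog3; SD, n = 3). Ribosomal protein genes took 7.23% ± 1.49 in the controls and 3.87% ± 0.997 and 3.87% ± 0.83 at day 13.

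**Figure D1:**
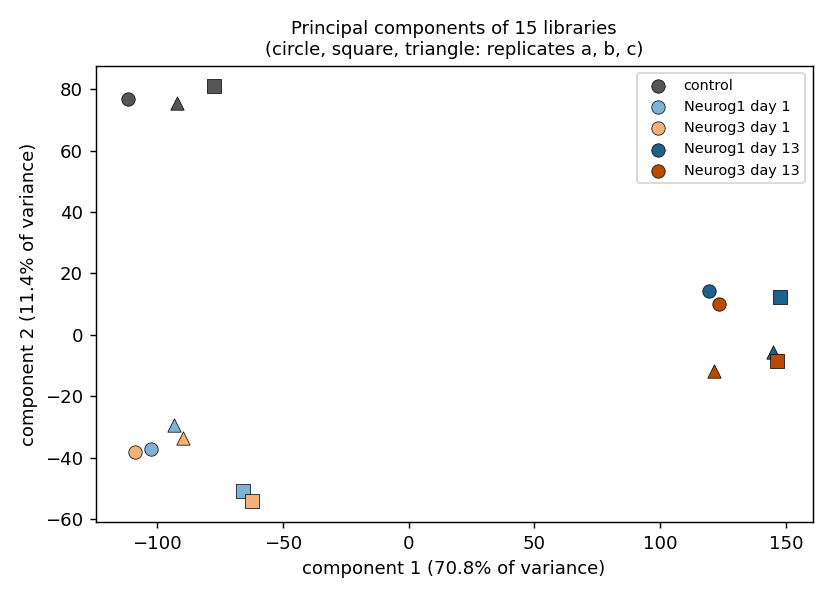
Principal components 1 and 2 of log2 CPM for the 15 libraries, 1 point per library, coloured by group, with circles, squares and triangles for replicates a, b and c. The day-13 libraries of both factors lie apart from the controls and the day-1 libraries along component 1, which holds 70.81% of the variance.

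Neurog1 at day 1 against the controls asked which genes differ after 24 h. Of the early proneural list, 14 of 30 genes rose, and 12 of 15 contractile, 10 of 19 muscle and 7 of 20 cholesterol genes fell. Dll1, the Notch ligand that proneural factors switch on (chromosome 17, 15367354 to 15376872), rose from 0.13 ± 0.113 to 53.5 ± 4.64 CPM (log2 fold change 8.63 ± 0.42, adjusted p = 1.58e-08, n = 3). Hes6, which promotes neuronal differentiation (chromosome 1, 91411483 to 91414038), rose from 18.6 to 166 CPM (3.15 ± 0.41, adjusted p = 9e-05). Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), fell from 4722 to 928 CPM (-2.35 ± 0.40, adjusted p = 0.000972). Of 16872 genes tested, 1144 rose and 914 fell by edgeR's quasi-likelihood test, 889 and 745 of them at least 2-fold. The 914 became 578 without Neurog1 day-1 replicate a and 563 without its replicate b.

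The highest folds at day 1 with Neurog1, after Neurog1 itself, were in genes nearly silent in the controls. The neuropeptide galanin, Gal, reached 409 CPM, 6563-fold with a 95% counting interval of 2246 to 31829. Sct, the hormone secretin, reached 152 CPM, 3606-fold with a 95% counting interval of 998 to 29778. Tekt1, a ciliary tektin, and Tff3, a trefoil peptide, had 0 control counts and rose at least 266-fold and at least 116-fold. Btbd17 rose 1171-fold with a 95% counting interval of 324 to 9675. Among the transcription factors, Neurod1 and Neurod2 came from 0 counts and rose at least 22.4-fold and at least 14-fold, and Insm1 rose 19.4-fold with a 95% counting interval of 6.31 to 96.6. Rcor2, a corepressor subunit, rose from 13.7 to 103 CPM (2.92 ± 0.34), Ebf3 rose by 1.23 ± 0.19 and Sox11 by 1.39 ± 0.20. Heyl, a Notch target, rose from 0.314 to 106 CPM (8.35 ± 0.60) and the receptor Notch2 rose by 1.74 ± 0.34. Slc17a7, a vesicular glutamate transporter, rose by 6.18 ± 0.84.

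Structural neuronal genes had not risen as a group at day 1 with Neurog1. Map2 fell (-2.15 ± 0.45, adjusted p = 0.00411), Stmn2 fell (-1.16 ± 0.35, adjusted p = 0.0429), and Dclk1 fell (-1.86 ± 0.30), while Crmp1 rose (1.21 ± 0.31, adjusted p = 0.0174). Tubb3 was not called (1.34 ± 0.52, adjusted p = 0.115). The largest falls by the naming rule were in the matricellular gene Ccn5 (-6.86 ± 0.80), Rtl3 (-6.17 ± 0.86), Aspn (-5.65 ± 0.71), Erg (-5.34 ± 1.07), Gjb2 (-5.05 ± 0.65) and Edn1 (-4.81 ± 1.04). Tagln, Tpm1 and Cald1, all actin-binding, fell (-1.50 ± 0.31, -1.27 ± 0.28 and -0.82 ± 0.25). Thbs1 fell (-2.90 ± 0.66), Postn fell (-1.24 ± 0.32) and Lox fell (-1.07 ± 0.32), but Col3a1 rose (1.90 ± 0.39, adjusted p = 0.00362). Col1a1 (-0.92 ± 0.60, adjusted p = 0.395), Vim (-0.75 ± 0.44, adjusted p = 0.334), Mki67 (-0.24 ± 0.24, adjusted p = 0.639) and Cdk1 (0.14 ± 0.30, adjusted p = 0.862) were not called.

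Of 29 lists, 7 passed camera's threshold for Neurog1 at day 1, and none of the 7 held with an estimated correlation. In the proneural list of 30 genes, 14 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 1.83 (1.59 with genes at their bounds; adjusted p = 1.53e-15, and adjusted p = 0.118 with an estimated correlation). In the Notch list of 18, 6 rose and 0 fell (7 and 1 adjusted over the list alone) (adjusted p = 1.28e-08, and adjusted p = 0.135 with an estimated correlation). Of 16 endocrine genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone), median 1.18 (adjusted p = 0.00267, and adjusted p = 0.182 with an estimated correlation). Contractile genes went down: of 15, 0 rose and 12 fell (0 and 14 adjusted over the list alone), median -1.70 (adjusted p = 1.07e-15, and adjusted p = 0.118 with an estimated correlation). Of 19 skeletal muscle genes, 1 rose and 10 fell (1 and 15 adjusted over the list alone), median -2.24 (adjusted p = 1.24e-06, and adjusted p = 0.374 with an estimated correlation). Actc1 fell (-3.49 ± 0.66) and Myod1 was lower by a ratio of 14.3-fold with a 95% counting interval of 4.58 to 72.1, whereas Chrna1, an acetylcholine receptor subunit, rose from 7.05 to 333 CPM (5.56 ± 0.70). Of 32 fibroblast and matrix genes, 2 rose and 8 fell (3 and 11 adjusted over the list alone), median -0.73 (adjusted p = 0.00145, and adjusted p = 0.614 with an estimated correlation). Of 20 cholesterol synthesis genes, 0 rose and 7 fell (0 and 9 adjusted over the list alone), among them Hmgcs1 (adjusted p = 0.0225) and Cyp51 (-0.83 ± 0.23) (adjusted p = 0.00203, and adjusted p = 0.614 with an estimated correlation). The cell cycle list was not called (1 rose and 0 fell of 26, adjusted p = 0.458), and its called member was E2f1 (1.96 ± 0.19).

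The comparison of Neurog3 at day 1 with the controls asked the same of the second factor, and many of the same genes moved. Dll1 rose to 72 ± 12.4 CPM (log2 fold change 9.06 ± 0.42, adjusted p = 8.07e-09, n = 3), and Hes6 rose to 99.3 CPM (2.42 ± 0.40, adjusted p = 0.000715). Acta2 fell to 813 CPM (-2.54 ± 0.40, adjusted p = 0.000563). The test called 1213 genes higher and 943 lower, 903 and 755 of them at least 2-fold. Gal rose 9742-fold with a 95% counting interval of 3333 to 47243 to 617 CPM, the highest ratio after Neurog3. C1ql2, a synaptic organiser of the C1q family, Tekt1, Tff3 and the pregnancy glycoprotein Psg22 all had 0 control counts and rose at least 249-fold, at least 168-fold, at least 137-fold and at least 125-fold. Sct rose 1138-fold with a 95% counting interval of 314 to 9399. Neurod1 and Neurod2 rose at least 27.9-fold and at least 40.2-fold, and Insm1 rose 23.9-fold with a 95% counting interval of 7.86 to 119.

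Other early genes with Neurog3 had values near those with Neurog1. Rcor2 (2.95 ± 0.34), Ebf3 (1.68 ± 0.19), Sox11 (1.02 ± 0.20), Heyl (8.48 ± 0.60), Notch2 (1.86 ± 0.34), Slc17a7 (6.19 ± 0.84), Homer1 (1.25 ± 0.22) and Chrna1 (5.56 ± 0.70) rose. Hes1, a Notch target that represses proneural genes, fell (-1.39 ± 0.39, adjusted p = 0.0264). Map2 (-2.44 ± 0.45, adjusted p = 0.00187) and Stmn2 (-1.42 ± 0.36, adjusted p = 0.0149) fell, and Tubb3 was not called (1.23 ± 0.52, adjusted p = 0.144). The lowest were Ccn5 (-6.65 ± 0.78), Aspn (-5.52 ± 0.70), Edn1 (-4.97 ± 1.05), the complement gene C1qc (-4.86 ± 1.34, adjusted p = 0.0247), Rtl3 (-4.77 ± 0.75) and Il1rn (-4.77 ± 0.60). Tagln (-1.79 ± 0.31), Thbs1 (-2.71 ± 0.66), Actc1 (-3.89 ± 0.67), Des (-1.37 ± 0.41, adjusted p = 0.0405) and Thy1, a fibroblast surface protein (-1.86 ± 0.49, adjusted p = 0.0203), fell, and Col3a1 rose (2.10 ± 0.39, adjusted p = 0.00178). Col1a1 (-1.05 ± 0.60, adjusted p = 0.298) and Mki67 (-0.05 ± 0.24, adjusted p = 0.937) were not called.

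For Neurog3 at day 1, 10 lists were called and none of the 10 held with an estimated correlation. Of 30 proneural genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), median 1.85 (1.59 with bounds; adjusted p = 1.22e-15, and adjusted p = 0.102 with an estimated correlation). The Notch list had 7 genes that rose and 1 that fell (8 and 1 adjusted over the list alone; adjusted p = 2.26e-09, and adjusted p = 0.102 with an estimated correlation). The endocrine list had 5 and 1 (adjusted p = 0.00863, and adjusted p = 0.252 with an estimated correlation). Of 15 contractile genes, 0 rose and 12 fell (0 and 14 adjusted over the list alone), median -1.81 (adjusted p = 5.68e-16, and adjusted p = 0.102 with an estimated correlation). Of 19 muscle genes, 1 rose and 12 fell (1 and 16 adjusted over the list alone) (adjusted p = 4.53e-08, and adjusted p = 0.303 with an estimated correlation). Of 32 fibroblast and matrix genes, 1 rose and 9 fell (2 and 10 adjusted over the list alone) (adjusted p = 0.00165, and adjusted p = 0.585 with an estimated correlation), and of 20 cholesterol genes, 0 rose and 4 fell (1 and 7 adjusted over the list alone) (adjusted p = 0.0312, and adjusted p = 0.711 with an estimated correlation).

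A further 3 lists passed with Neurog3 only: glutamatergic (3 of 7 rose, adjusted p = 0.0312, and adjusted p = 0.263 with an estimated correlation), stress and immediate early (2 of 18 fell, 5 adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.585 with an estimated correlation) and macrophage (1 rose and 2 fell of 13, 7 fell adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.644 with an estimated correlation). Fos (-2.57 ± 0.63) and Lyz2 (-3.07 ± 0.87, adjusted p = 0.0295) were among the genes that fell, and Itgam rose (2.06 ± 0.34). With Neurog1 these lists had adjusted p = 0.0642, 0.0661 and 0.0866. The direct test between the factors at day 1 did not call them either (adjusted p = 0.717, 0.543 and 0.062), but with the replicate block within day the macrophage list was lower with Neurog3 (adjusted p = 0.00933, and adjusted p = 0.986 with an estimated correlation).

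Lists not called in either day-1 comparison included cytoskeleton (2 rose and 4 fell of 28 with Neurog1, adjusted p = 0.45; 2 and 3 with Neurog3, 0.37) and synapse (4 and 3 of 30, 0.185; 5 and 3, 0.127). Adjusted over the list alone the cytoskeleton counts were 2 and 5 with Neurog1 and 2 and 4 with Neurog3, and the synapse counts 5 and 3, and 7 and 3. The cytoskeleton list's median was -0.10 and its mean 0.02 with Neurog3, so these differ in sign. Glycolysis (0.148 and 0.0683) and ion channels (0.803 and 0.644) were also not called. Single genes in uncalled lists still changed with both factors: Krt8 rose (3.37 ± 0.47 with Neurog1, 3.27 ± 0.47 with Neurog3), Mmp3 rose (2.31 ± 0.40 and 2.28 ± 0.40), Kdr fell (-4.21 ± 0.94 and -3.72 ± 0.91), and Slc1a3 fell (-2.65 ± 0.30 and -2.73 ± 0.30).

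**Figure D2:**
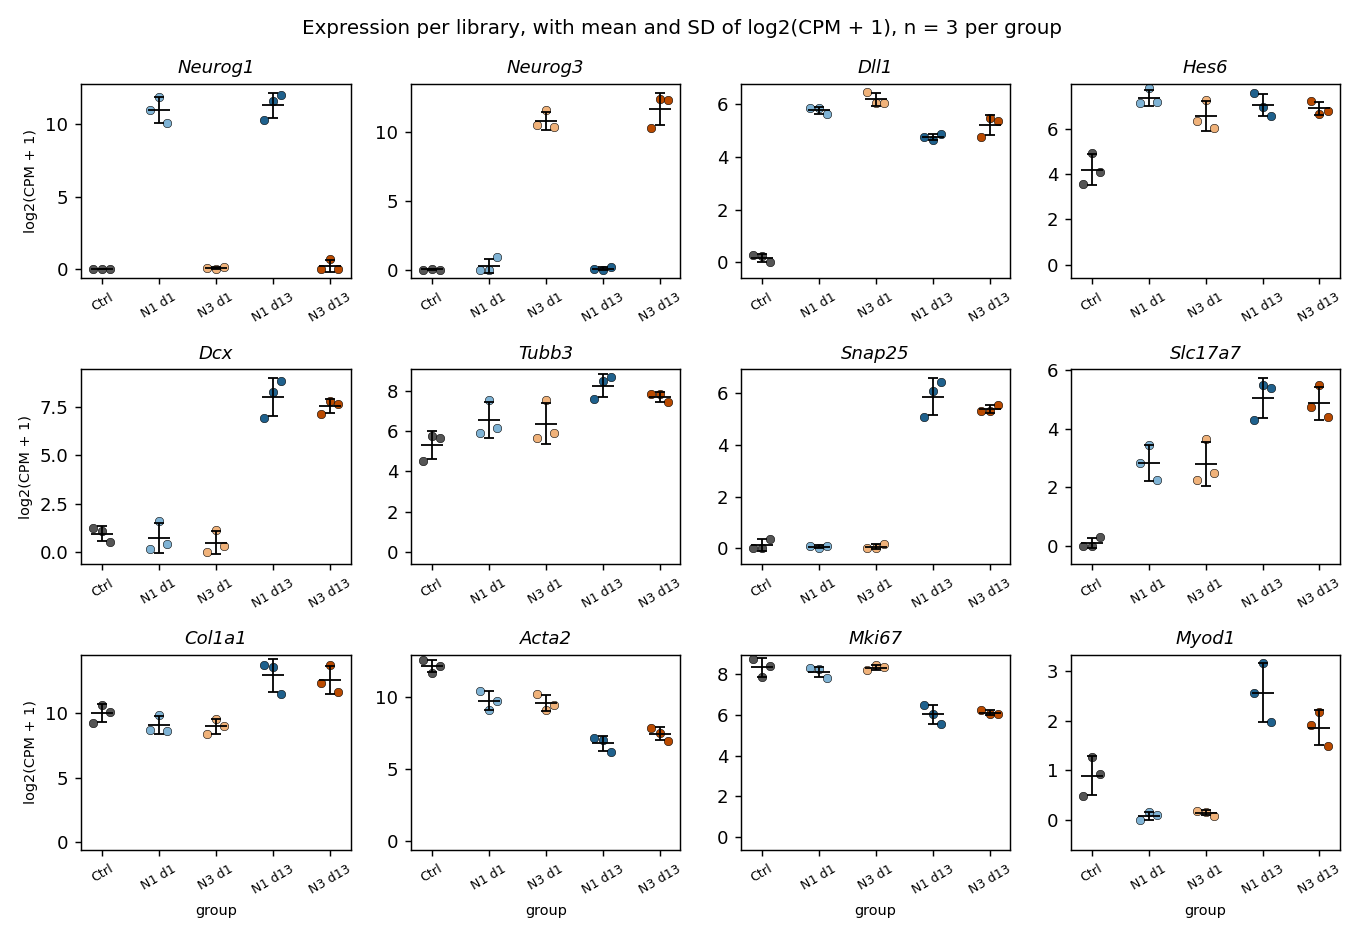
Expression of 12 genes as log2(CPM + 1) in the 15 libraries, 1 point per library, with the mean and SD of each group (n = 3). Dll1 is near 0 in the controls and present in all 12 libraries with a factor, whereas Dcx and Snap25 are low at day 1 and high in the 6 libraries of day 13.

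The day-13 comparisons asked what the cells express once the neuronal medium has been in place, and the controls carry no day-13 label. With Neurog1, 26 of 28 neuronal cytoskeleton, 27 of 30 synapse and 24 of 28 channel genes rose, and 14 of 15 contractile, 25 of 26 cell cycle and 12 of 16 glycolysis genes fell. Dcx, a microtubule protein of young neurons (chromosome X, 143855842 to 143933311), rose from 0.989 ± 0.504 to 293 ± 165 CPM (log2 fold change 8.21 ± 0.83, adjusted p = 1.34e-06, n = 3). Tubb3 rose from 41.9 to 325 CPM (2.96 ± 0.55, adjusted p = 0.000308) and Map2 from 18.8 to 108 CPM (2.53 ± 0.43, adjusted p = 0.000146). Col1a1, the fibrillar collagen (chromosome 11, 94936224 to 94953042), rose from 1096 to 9700.5 CPM (3.15 ± 0.64, adjusted p = 0.000677). Acta2 fell to 115 CPM (-5.36 ± 0.46, adjusted p = 3.48e-07). The test called 5495 genes higher and 4521 lower, 4263 and 3038 of them at least 2-fold. Higher genes were 54.9% of those called, and 67.3% (6762 higher, 3285 lower) with scaling by library totals, which moved the median log2 fold change of all genes from 0.10 to 0.40.

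Synaptic and channel genes at day 13 with Neurog1 had high folds. Snap25, a vesicle fusion protein, rose from 0.101 to 62.1 CPM (9.11 ± 0.67) and Syn1 rose by 4.87 ± 0.45. Kcna1 rose by 7.83 ± 0.40, Scn3a by 6.67 ± 0.67 and Cacna1e by 10.12 ± 0.88. Mmd2, Igsf21, the helix-loop-helix factor Nhlh2 and the calcium sensor Hpca came from 0 control counts and rose at least 1592-fold, at least 1184-fold, at least 1111-fold and at least 1036-fold. Neurod1 reached 55 CPM (at least 882-fold), Rbfox3, the marker of mature neurons known as NeuN, 22.9 CPM (549.9-fold (152 to 4546)), and Myt1l rose 1372-fold (246 to 54221). Endocrine-associated Insm1 reached 61.6 CPM (976-fold (334 to 4734)), Chgb 60.7 CPM (953-fold (326 to 4622)) and Sct 154 CPM (3613-fold (999.9 to 29839.5)).

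Among transmitter genes at day 13 with Neurog1, those of vesicular glutamate transport rose. Slc17a7 rose from 0.0805 to 34.4 CPM (8.56 ± 0.83, adjusted p = 9.43e-07) and Slc17a6 to 3.48 CPM (2.54 ± 0.48, adjusted p = 0.000375). Chat, the acetylcholine-synthesising enzyme, reached 0.869 CPM and Th, of catecholamine synthesis, 0.789 CPM. Gad1, of GABA synthesis, had 3 counts over the 3 libraries at day 13 with Neurog1 and 7 with Neurog3. The sensory factor Pou4f1 reached 14 CPM (677-fold (121 to 26766)). P2rx3 (4.95 ± 0.57) and Ret (5.15 ± 0.49) rose, Runx1 fell (-1.44 ± 0.27) and Isl1 was not called (-0.95 ± 0.40, adjusted p = 0.0522). The insulin gene Ins1 had 0 counts in all 15 libraries. Ins2 had 0 counts in 12 libraries and 4, 1 and 5 in the Neurog3 day-13 libraries, below the expression filter.

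Fibroblast genes went both ways at day 13 with Neurog1. Col1a2 (3.17 ± 0.60), Col3a1 (4.01 ± 0.42) and Sparc (2.02 ± 0.30) rose, Vim fell from 6109.6 to 734 CPM (-3.06 ± 0.47), Thy1 fell (-3.86 ± 0.54) and Twist1 was not called (0.08 ± 0.23, adjusted p = 0.778). Tagln (-4.33 ± 0.35) and Tpm1 (-2.94 ± 0.30) fell. Proliferation genes fell: Mki67 (-2.31 ± 0.26), Cdk1 (-2.60 ± 0.32) and Top2a (-2.52 ± 0.32). The cycle inhibitor Cdkn1c rose (1.14 ± 0.26, adjusted p = 0.00171). Eno1 fell from 2695 to 201 CPM (-3.75 ± 0.41), and Msmo1 of cholesterol synthesis fell (-3.08 ± 0.26). Among the lowest folds, Lce1h, U90926 and Wfdc2 had 0 counts at day 13, at least 179-fold, at least 107-fold and at least 104-fold lower. F2rl1 fell (-8.93 ± 0.80), and Esm1 and the keratin Krt18 were lower by ratios of 632-fold (113 to 24999) and 536-fold (148 to 4437).

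With Neurog1, 15 lists were called at day 13 against the controls. Of 30 proneural genes, 28 rose and 0 fell, median 7.08 (6.81 with bounds; adjusted p = 1.16e-21, or 0.0564 with an estimated correlation). The cytoskeleton list had 26 of 28 up and 0 down (adjusted p = 1.46e-12, or 0.103 with an estimated correlation), and the synapse list 27 of 30 up (adjusted p = 1.8e-19, or 0.0564 with an estimated correlation). The channel list had 24 of 28 up (median 5.46, 5.24 with bounds; adjusted p = 8.46e-14, or 0.0564 with an estimated correlation). Glutamatergic genes had 5 of 7 up (adjusted p = 0.00144, or 0.0751 with an estimated correlation), sensory genes 13 up and 3 down of 19 (adjusted p = 0.00706, or 0.0564 with an estimated correlation), and Notch genes 14 up and 1 down of 18 (adjusted p = 1.96e-06, or 0.107 with an estimated correlation). The endocrine list had 13 of 16 up, median 7.42 (6.97 with bounds; adjusted p = 1.18e-10), and held with an estimated correlation (0.0195). These 16 are the members that passed the expression filter, which left out Ins1 and Ins2, and Insm1 and Neurod1 are also in the proneural list. The counts above were the same adjusted over the list alone, except 4 sensory genes and 1 endocrine gene that fell.

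Lists that went down at day 13 with Neurog1 were contractile (14 of 15, median -3.52; adjusted p = 8.46e-14, and adjusted p = 0.0564 with an estimated correlation), cell cycle (25 down and 1 up of 26, median -2.26; adjusted p = 1.46e-12, and adjusted p = 0.164 with an estimated correlation) and cholesterol synthesis (17 of 20; adjusted p = 7.47e-09, and adjusted p = 0.179 with an estimated correlation). Glycolysis (12 of 16; adjusted p = 6.08e-08, and adjusted p = 0.139 with an estimated correlation), inflammatory genes (10 down and 1 up of 15; adjusted p = 0.000342, and adjusted p = 0.179 with an estimated correlation) and epithelial genes (5 of 6, median -7.11, -5.88 with bounds; adjusted p = 0.00133, and adjusted p = 0.139 with an estimated correlation) also went down. These counts were unchanged adjusted over each list alone. The interferon list went up, with 16 of 20 higher and 1 lower (adjusted p = 0.0107, and adjusted p = 0.755 with an estimated correlation), among them Bst2 (2.49 ± 0.59) and Stat2 (1.79 ± 0.36).

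The remaining 14 lists were not called at day 13 with Neurog1. The fibroblast and matrix list had 15 up and 8 down of 32 (adjusted p = 0.536), skeletal muscle 3 and 3 of 19 (0.9), and inhibitors and p53 targets 4 and 6 of 16 (0.47). The GABAergic list had 3 and 3 of 9 (0.964), the cholinergic and motor list 5 and 1 of 7 (0.373), the monoaminergic list 3 and 1 of 6 (0.9) and the neural progenitor list 4 and 2 of 10 (0.786). Stress genes had 2 and 3 of 18 (0.693; median 0.02, mean -0.05), macrophage genes 1 and 2 of 13 (0.497) and endothelial genes 1 and 1 of 6 (0.497). Adipocyte genes had 3 and 3 of 6 (0.828; median -0.21, mean 0.85), cartilage and bone 2 and 5 of 9 (0.398), astrocyte and oligodendrocyte 5 and 1 of 10 (0.47), and neural crest and Schwann 2 and 0 of 11 (0.9). Adjusted over the list alone, the counts differed in 5 of these lists: cholinergic and motor (5 up, 2 down), inhibitors and p53 targets (5 and 6), stress (2 and 2), macrophage (1 and 0), and cartilage and bone (3 and 5). Among their members, Nes, an intermediate filament of progenitors, fell (-3.88 ± 0.48), Spp1 fell (-6.45 ± 1.26), and Lpl (1.37 ± 0.29), Slc1a3 (0.88 ± 0.27) and Ngfr (4.32 ± 0.84) rose.

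**Figure D3:**
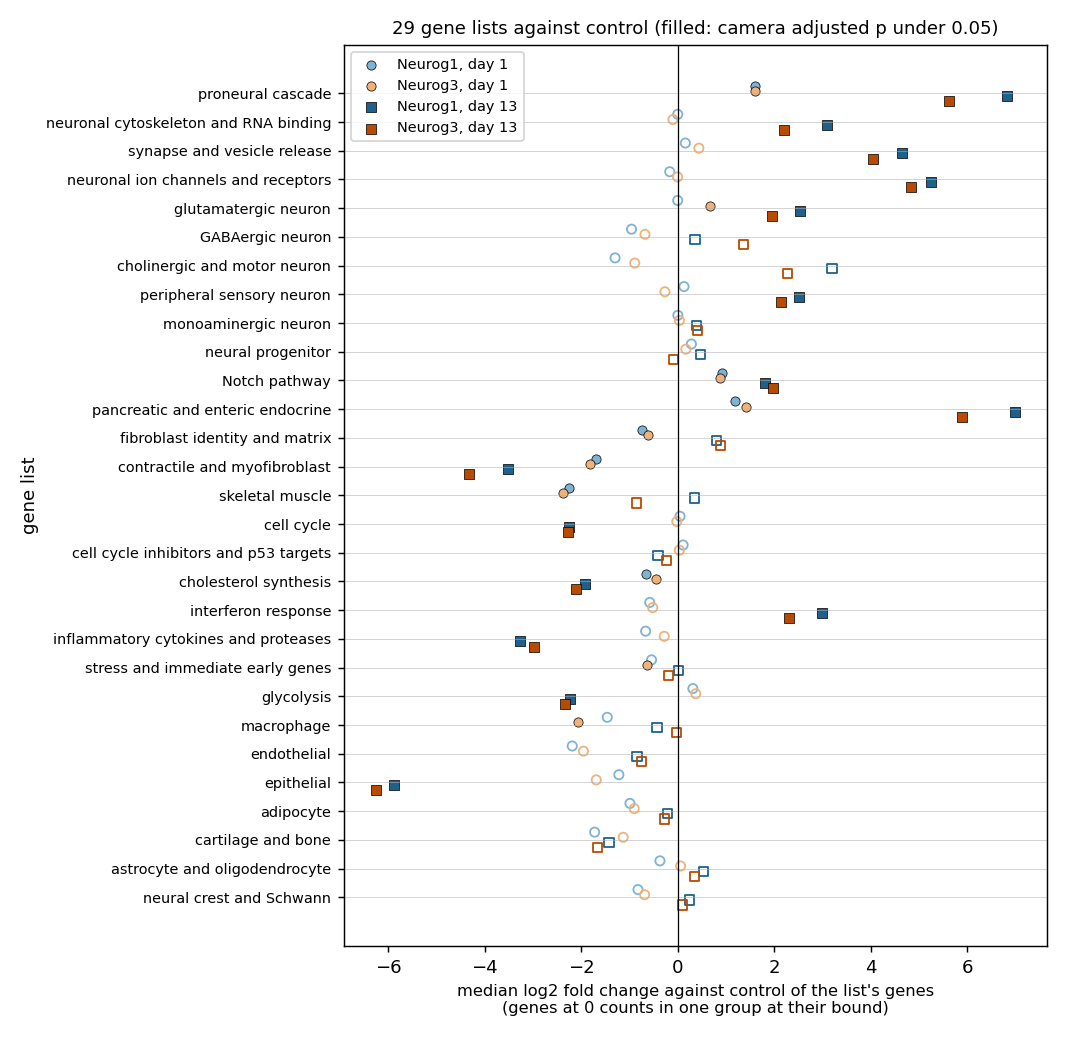
Median log2 fold change of each of the 29 gene lists (x axis), with genes at their bounds, in the 4 comparisons with the controls, filled where camera called the list. At day 13 the proneural, cytoskeleton, synapse, channel and endocrine lists lie on the right, and the contractile, cell cycle, glycolysis and epithelial lists on the left. The GABAergic, cholinergic and monoaminergic lists were not called at day 13.

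Neurog3 at day 13 against the controls changed many of the same genes as Neurog1. Dcx rose to 189.5 ± 43.7 CPM (log2 fold change 7.58 ± 0.81, adjusted p = 2.3e-06, n = 3), Tubb3 to 210.4 CPM (2.33 ± 0.54, adjusted p = 0.0017) and Map2 to 76.8 CPM (2.04 ± 0.42, adjusted p = 0.000801). Col1a1 rose to 7355 CPM (2.75 ± 0.63, adjusted p = 0.00173) and Acta2 fell to 181 CPM (-4.70 ± 0.45, adjusted p = 8.36e-07). The test called 5260 genes higher and 4459 lower, 4044 and 3040 of them at least 2-fold. Higher genes were 54.1% of those called, and 67.5% (6663 higher, 3211 lower) with library totals, which moved the median of all genes from 0.10 to 0.40. High folds came from 0 control counts: Mmd2 rose at least 2294-fold, the sulfotransferase Hs3st2 at least 1185-fold, Nhlh2 at least 951-fold and Hpca at least 952-fold.

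Neuronal genes that rose at day 13 with Neurog3 included Snap25 (8.51 ± 0.67), Syn1 (4.30 ± 0.45), Stmn2 (1.12 ± 0.35, adjusted p = 0.0121) and Slc17a7 (8.34 ± 0.83). Neurod1 rose at least 324-fold, Rbfox3 722-fold (199.5 to 5965), Insm1 1028-fold (351 to 4985), Chgb 746-fold (255 to 3618), Sct 4198-fold (1162 to 34669) and Pou4f1 522-fold (93.4 to 20666). Chat reached 2.08 CPM and Th 1.77 CPM. Gap43, a growth cone protein, fell (-1.06 ± 0.39, adjusted p = 0.0287), as did Dpysl3 (-0.68 ± 0.27, adjusted p = 0.0406) and Isl1 (-1.36 ± 0.41, adjusted p = 0.0103). Vim (-3.28 ± 0.48), Thy1 (-3.78 ± 0.54), Tagln (-4.38 ± 0.35), Mki67 (-2.26 ± 0.26), Eno1 (-3.62 ± 0.41), Msmo1 (-3.40 ± 0.27) and Twist1 (-0.63 ± 0.23, adjusted p = 0.0286) fell, and Cdkn1c was not called (0.43 ± 0.26, adjusted p = 0.171). Among the lowest folds were Esm1, at least 201-fold lower, Lce1h, at least 171-fold lower, F2rl1, lower by a ratio of 1025-fold (283 to 8472), Il1rl1 (from 636 to 1.24 CPM) and Slc14a1 (-8.96 ± 0.94).

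The same 15 lists were called with Neurog3 at day 13. Proneural genes rose in 28 of 30 cases (median 6.51, 5.62 with bounds; adjusted p = 1.85e-21), and the endocrine list had 12 up and 1 down of 16 (14 and 1 adjusted over the list alone; adjusted p = 1.8e-10). These 2 lists held with an estimated correlation (0.0491 and 0.017). Cytoskeleton had 22 up and 2 down (adjusted p = 1e-08, and adjusted p = 0.143 with an estimated correlation), synapse 27 up (adjusted p = 1.79e-16, and adjusted p = 0.0765 with an estimated correlation) and channels 23 up and 1 down (adjusted p = 1.04e-11, and adjusted p = 0.0765 with an estimated correlation). Glutamatergic (6 up; adjusted p = 0.0025, and adjusted p = 0.0765 with an estimated correlation), sensory (12 up and 5 down, 13 up adjusted over the list alone; adjusted p = 0.0305, and adjusted p = 0.101 with an estimated correlation) and Notch genes (15 up and 1 down; adjusted p = 7.28e-07, and adjusted p = 0.122 with an estimated correlation) followed. Contractile (14 down; adjusted p = 5.81e-14, and adjusted p = 0.0765 with an estimated correlation), cell cycle (25 down; adjusted p = 2.72e-12, and adjusted p = 0.16 with an estimated correlation) and cholesterol genes (17 down, 18 adjusted over the list alone; adjusted p = 4.55e-11, and adjusted p = 0.147 with an estimated correlation) were lower. So were glycolysis (12 down, 13 adjusted over the list alone; adjusted p = 1.25e-08, and adjusted p = 0.143 with an estimated correlation), inflammatory (10 down, 11 adjusted over the list alone; adjusted p = 9.17e-05, and adjusted p = 0.147 with an estimated correlation) and epithelial genes (5 down; adjusted p = 0.00386, and adjusted p = 0.16 with an estimated correlation). Interferon genes had 15 up and 1 down (adjusted p = 0.0411, and adjusted p = 0.786 with an estimated correlation).

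Day 13 against day 1 with Neurog1 asked what changed while the factor stayed on, across the medium change. Dcx rose from 0.842 to 293 CPM (log2 fold change 8.38 ± 0.84, adjusted p = 1.53e-06, n = 3), Map2 rose (4.69 ± 0.48, adjusted p = 1.95e-06) and Stmn2 rose (3.65 ± 0.38, adjusted p = 2.23e-06), both having fallen at day 1. Dll1 fell from 53.5 to 25.9 CPM (-1.04 ± 0.25, adjusted p = 0.00245), and Gal fell from 409 to 3.2 CPM (-6.99 ± 0.49, adjusted p = 8.84e-08). The test called 5163 genes higher and 4603 lower, 4108 and 3088 of them at least 2-fold. Higher genes were 52.9% of those called, and 65.4% (6438 higher, 3411 lower) with library totals, which moved the median of all genes from 0.08 to 0.37. From 0 counts at day 1, Stmn3 rose at least 1592-fold, Slitrk1 at least 922-fold, Eef1a2 at least 772-fold, Hrk at least 438-fold, Phf24 at least 408-fold and Ostn at least 349-fold. Snap25 rose 1488-fold (412 to 12296).

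Genes that fell from day 1 to day 13 with Neurog1 included some that had risen at day 1. Heyl fell (-3.81 ± 0.44), Chrna1 fell (-7.72 ± 0.79) and Mcpt8 fell (-8.89 ± 0.61). Wincr1, Tff3, Mmp10 and Psg22 went to 0 counts, at least 159-fold, at least 140.5-fold, at least 125-fold and at least 110.3-fold lower, and Krt18 was lower by a ratio of 720.3-fold (199 to 5955). Hes6 (-0.29 ± 0.37, adjusted p = 0.522) and Sct (0.02 ± 0.49, adjusted p = 0.976) were not called. Col1a1 rose (4.07 ± 0.67), and Postn rose (2.21 ± 0.33) after falling at day 1. Myod1 rose 83.1-fold (28.2 to 405). Mki67 (-2.07 ± 0.25), Top2a (-2.57 ± 0.32), Eno1 (-3.71 ± 0.41) and Acta2 (-3.02 ± 0.41) fell, and Bst2 rose (2.94 ± 0.60).

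Of the 16 lists called for Neurog1 between the days, those up were proneural (24 up and 1 down; adjusted p = 1.5e-10, and adjusted p = 0.127 with an estimated correlation), cytoskeleton (26 up; adjusted p = 1.14e-14, and adjusted p = 0.11 with an estimated correlation), synapse (27 up and 1 down; adjusted p = 1.16e-17, and adjusted p = 0.0872 with an estimated correlation) and channels (26 up; adjusted p = 4.69e-16, and adjusted p = 0.0821 with an estimated correlation). Glutamatergic (5 up; adjusted p = 0.0183, and adjusted p = 0.192 with an estimated correlation), sensory (11 up and 2 down; adjusted p = 0.00248, and adjusted p = 0.0821 with an estimated correlation) and interferon genes (17 up; adjusted p = 0.000815, and adjusted p = 0.637 with an estimated correlation) were up as well. The endocrine list (10 up; adjusted p = 1.27e-07) held with an estimated correlation (0.0362). Fibroblast and matrix (18 up and 5 down; adjusted p = 0.0207, and adjusted p = 0.637 with an estimated correlation) and skeletal muscle genes (13 up and 1 down; adjusted p = 0.0231, and adjusted p = 0.637 with an estimated correlation) were up. Down were contractile (11; adjusted p = 2.34e-05, and adjusted p = 0.234 with an estimated correlation), cell cycle (26; adjusted p = 1.14e-14, and adjusted p = 0.172 with an estimated correlation), cholesterol (14; adjusted p = 2.34e-05, and adjusted p = 0.361 with an estimated correlation), inflammatory (10; adjusted p = 0.00101, and adjusted p = 0.234 with an estimated correlation), glycolysis (13; adjusted p = 2.9e-10, and adjusted p = 0.132 with an estimated correlation) and epithelial genes (4; adjusted p = 0.00778, and adjusted p = 0.234 with an estimated correlation). Adjusted over the list alone, 25 proneural and 27 cytoskeleton genes and 1 inflammatory gene rose, 4 sensory, 6 fibroblast and 14 glycolysis genes fell, and the other counts were unchanged.

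Day 13 against day 1 with Neurog3 moved many of the same genes as with Neurog1. Dcx rose from 0.49 to 189.5 CPM (log2 fold change 8.50 ± 0.86, adjusted p = 1.99e-06, n = 3), Map2 rose (4.47 ± 0.48, adjusted p = 3.28e-06) and Dll1 fell (-0.98 ± 0.25, adjusted p = 0.00404). Tubb3 was not called (1.10 ± 0.52, adjusted p = 0.0806), while with Neurog1 it was (1.61 ± 0.52, adjusted p = 0.015). The interaction test did not call Tubb3 (-0.51 ± 0.72, adjusted p = 1). The test called 4887 genes higher and 4523 lower, 3801 and 3001 of them at least 2-fold. Higher genes were 51.9% of those called, and 63.1% (5916 higher, 3459 lower) with library totals, which moved the median of all genes from 0.07 to 0.31. Among the top genes were Cplx1, Slitrk1, Mapk8ip2, Eef1a2 and Gria2, which came from 0 counts and rose at least 922-fold, at least 649.5-fold, at least 574-fold, at least 393-fold and at least 365-fold. Snap25 rose 973-fold (269 to 8042) and Sct rose (1.88 ± 0.51, adjusted p = 0.00535).

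Among the genes that fell with Neurog3 between the days, Wincr1, Psg22 and Mmp10 went to 0 counts, at least 164-fold, at least 144-fold and at least 133-fold lower. Krt8, Mcpt8 and F2rl1 were lower by ratios of 1366-fold (245 to 53981), 1113-fold (308 to 9195) and 654-fold (180.5 to 5403). Heyl (-2.66 ± 0.42), Chrna1 (-7.36 ± 0.78), Gal (-8.34 ± 0.52), Mki67 (-2.21 ± 0.26) and Eno1 (-3.53 ± 0.41) fell, and Col1a1 (3.80 ± 0.66) rose. The 15 lists called were those of Neurog1 without skeletal muscle (9 up and 2 down, adjusted p = 0.213). The muscle list differed between the factors in the interaction (adjusted p = 0.00396, and adjusted p = 0.8 with an estimated correlation). Proneural genes had 24 up (adjusted p = 7.48e-11, and adjusted p = 0.0998 with an estimated correlation), cytoskeleton 21 (adjusted p = 3.88e-11, and adjusted p = 0.121 with an estimated correlation), synapse 27 (adjusted p = 6.01e-15, and adjusted p = 0.0998 with an estimated correlation) and channels 25 (adjusted p = 1.51e-14, and adjusted p = 0.0929 with an estimated correlation). The endocrine list (12 up, 14 adjusted over the list alone; adjusted p = 1.22e-08) held with an estimated correlation (0.0386). Cell cycle genes had 26 of 26 down (adjusted p = 1.51e-14, and adjusted p = 0.196 with an estimated correlation) and glycolysis 14 of 16, 15 adjusted over the list alone (adjusted p = 5.64e-12, and adjusted p = 0.0998 with an estimated correlation).

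The other 8 of these 15 lists lost their call with an estimated correlation as well. Between the days with Neurog3, glutamatergic genes had 5 up and 0 down (adjusted p = 0.0313, and adjusted p = 0.213 with an estimated correlation), sensory 11 and 5 (adjusted p = 0.0097, and adjusted p = 0.0998 with an estimated correlation), interferon 15 and 1 (adjusted p = 0.00986, and adjusted p = 0.659 with an estimated correlation), and fibroblast and matrix genes 19 and 8, or 20 and 8 adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.647 with an estimated correlation). Contractile genes had 0 up and 11 down (adjusted p = 1.6e-05, and adjusted p = 0.225 with an estimated correlation), cholesterol 0 and 16 (adjusted p = 8.57e-09, and adjusted p = 0.225 with an estimated correlation), inflammatory 0 and 9 (adjusted p = 0.000103, and adjusted p = 0.213 with an estimated correlation) and epithelial genes 1 and 4 (adjusted p = 0.0193, and adjusted p = 0.288 with an estimated correlation).

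Overlap asked if the factors change the same genes. At day 1, 966 genes rose and 730 fell under both factors, and 0 went opposite ways. These are 84.4% and 79.9% of the genes called with Neurog1, where independent lists would share 82.3 and 51.1. At day 13, 4853 genes rose and 4037 fell under both against the controls, and 1 went opposite ways, where independent lists would share 1713 and 1195. Pearson's r of the log2 fold changes, across genes, was 0.902 at day 1 and 0.971 at day 13. Sharing the controls alone gave r = 0.505 and 0.522 in 20 simulations of unchanged groups, in which 0 genes were called under both. The covariance exceeded the simulated one by 1.15 and 4.48, and part of the excess may come from the shared controls. Day 13 against day 1 shares no libraries between the factors, and there 4302 genes rose and 3954 fell under both, 1 went opposite ways, and r was 0.942 against a simulated 0.00309. Both factors share the medium change and the days in culture, which the simulations do not contain. The agreement at day 13 therefore cannot be assigned to the factors alone.

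**Figure D4:**
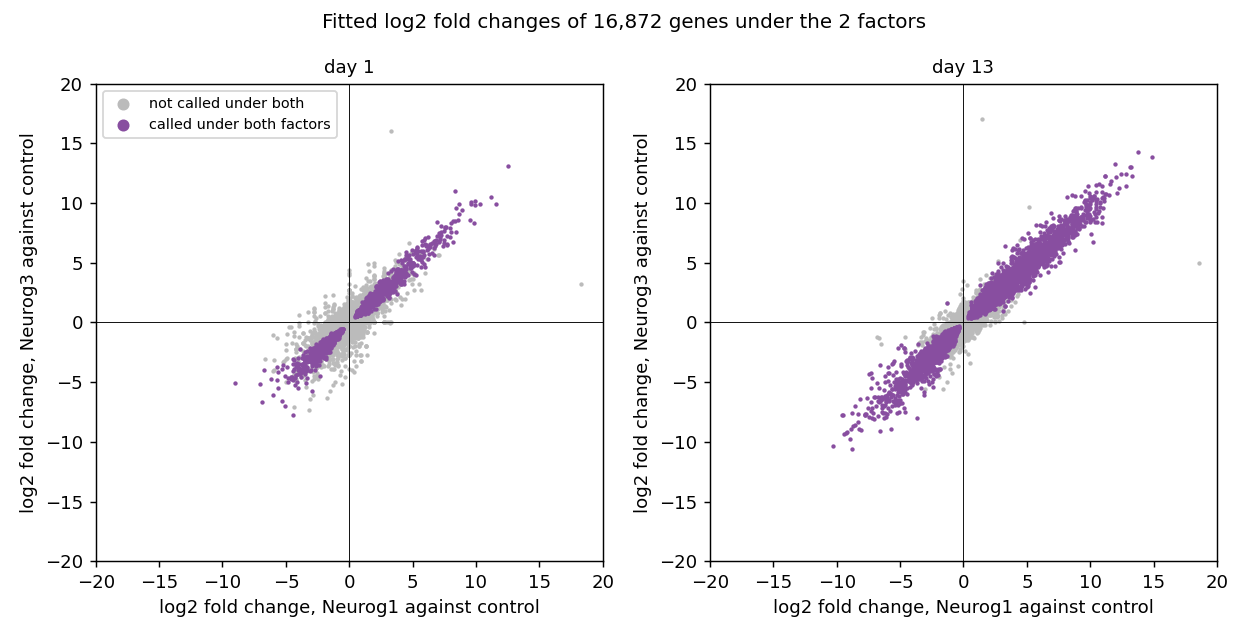
Log2 fold change against the controls with Neurog1 (x axis) and with Neurog3 (y axis) for each tested gene, at day 1 and at day 13. Points lie along the diagonal, with r = 0.902 at day 1 and 0.971 at day 13, with the points of Neurog1 and Neurog3 off it.

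The direct comparison of the factors at day 1 called the delivered genes alone. Neurog3 was higher in its own group (log2 fold change 12.71 ± 0.97, adjusted p = 1.42e-05, n = 3) and Neurog1 lower (-15.00 ± 1.09, adjusted p = 1.97e-05). At an unadjusted p under 0.05 there were 286 genes where 844 would come by chance, and DESeq2 called 2 higher and 2 lower. This test leaves out the pairing of the letters, so a count under chance does not show that the factors act alike. Dll1 differed by 0.43 ± 0.25 (95% interval -0.10 to 0.96), Hes6 by -0.74 ± 0.38 (-1.54 to 0.06), Slc17a7 by 0.01 ± 0.52 (-1.09 to 1.10) and Col1a1 by -0.13 ± 0.59 (-1.39 to 1.13), none of these 4 called. None of the 29 lists was called at day 1; the macrophage list came nearest (adjusted p = 0.062).

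With the replicate block within day, 9 genes were higher and 18 lower with Neurog3 at day 1, and 1036 had an unadjusted p under 0.05. The genes named here were chosen after their values were seen. Higher with Neurog3 were Ttyh1, a chloride channel of neural cells (1.08 ± 0.13, adjusted p = 0.00453), Mmd2 (1.21 ± 0.15, adjusted p = 0.00957) and C1ql2 (2.59 ± 0.38, adjusted p = 0.0214). Lower were Insc, which orients dividing progenitors (-2.73 ± 0.26, adjusted p = 0.000643), Sct (-1.73 ± 0.16, adjusted p = 0.000643) and Ch25h (-1.51 ± 0.17, adjusted p = 0.00453). Sct stood at 152 ± 61.4 CPM with Neurog1 and 48.5 ± 25.1 with Neurog3. Without letter a, b or c the counts of higher and lower genes were 12 and 10, 2 and 5, and 3 and 6. Camera called 5 lists in this fit: cholesterol synthesis (adjusted p = 0.00933, and adjusted p = 0.986 with an estimated correlation) and interferon response (adjusted p = 0.0488, and adjusted p = 0.986 with an estimated correlation) higher with Neurog3, and macrophage (adjusted p = 0.00933, and adjusted p = 0.986 with an estimated correlation), skeletal muscle (adjusted p = 0.0389, and adjusted p = 0.986 with an estimated correlation) and endocrine genes (adjusted p = 0.0488, and adjusted p = 0.986 with an estimated correlation) lower.

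At day 13 the factors differed in 4 genes, and neuronal cytoskeleton genes were lower as a list with Neurog3 (adjusted p = 8.52e-14, and adjusted p = 0.27 with an estimated correlation). Neurog3 was higher (log2 fold change 15.60 ± 1.10, adjusted p = 3.94e-06, n = 3) and Neurog1 lower (-13.61 ± 0.99, adjusted p = 2.01e-05). Ccbe1, a secreted factor of lymphatic growth (chromosome 18, 66045302 to 66302741), was lower with Neurog3, at 15.8 ± 5.26 against 69.9 ± 28.4 CPM (-2.14 ± 0.33, adjusted p = 0.0366). Fam19a1, a secreted brain peptide (chromosome 6, 96113154 to 96657198), stood at 1.34 ± 0.378 against 5.12 ± 0.72 CPM (-1.93 ± 0.28, adjusted p = 0.0262). There were 934 genes with an unadjusted p under 0.05 where 844 would come by chance, and DESeq2 called 30 higher and 56 lower. The 3 lower calls became 1 without Neurog1 replicate b, Neurog3 replicate a or Neurog3 replicate c, and 5 without Neurog1 replicate a. The 1 higher call became 2 without Neurog3 replicate a or b. Stmn2 (-1.38 ± 0.35, adjusted p = 0.3) and Neurod1 (-1.42 ± 0.47, adjusted p = 0.576) were not called. Tubb3 differed by -0.63 ± 0.51 (95% interval -1.71 to 0.46), Map2 by -0.50 ± 0.40 (-1.36 to 0.36), Insm1 by 0.08 ± 0.26 (-0.47 to 0.62) and Slc17a7 by -0.22 ± 0.49 (-1.26 to 0.83).

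Camera called 6 lists lower with Neurog3 than with Neurog1 at day 13, and none of the 6 held with an estimated correlation. The cytoskeleton list had a median difference of -0.66, with 0 genes called over all genes and 11 lower adjusted over the list alone (adjusted p = 8.52e-14, and adjusted p = 0.27 with an estimated correlation). The synapse list had a median of -0.42 (1 lower adjusted over the list alone; adjusted p = 2.21e-06, and adjusted p = 0.311 with an estimated correlation), channels -0.49 (adjusted p = 7.04e-06, and adjusted p = 0.277 with an estimated correlation), sensory genes -0.42 (adjusted p = 0.0408, and adjusted p = 0.27 with an estimated correlation), skeletal muscle -0.96 (adjusted p = 3.18e-08, and adjusted p = 0.277 with an estimated correlation) and cholesterol synthesis -0.32 (adjusted p = 0.00158, and adjusted p = 0.751 with an estimated correlation). The proneural list was not called (median -0.20, adjusted p = 0.241), nor was the endocrine list (-0.22, 0.394). By pair of libraries with the same letter, the cytoskeleton median was -0.07, -0.67 and -1.21 for a, b and c, and the synapse median -0.01, -0.33 and -0.93.

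**Figure D5:**
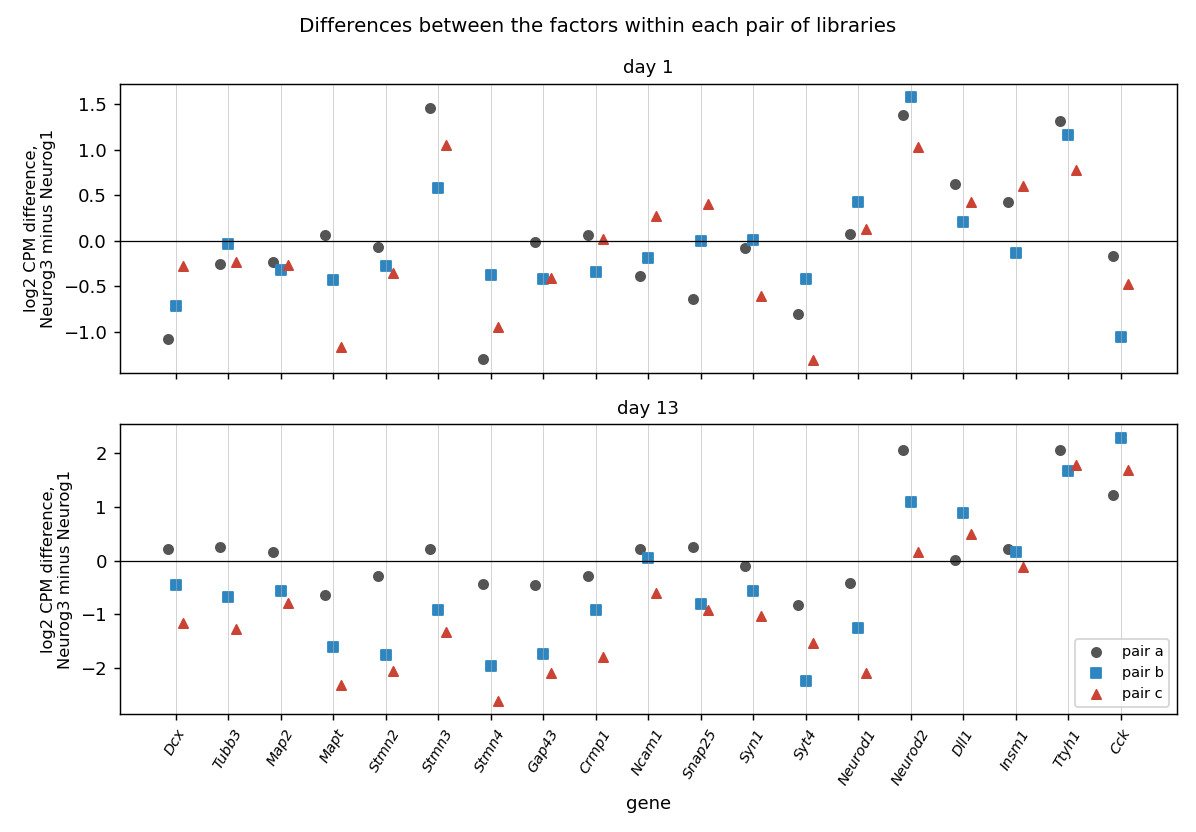
Log2 CPM difference, Neurog3 minus Neurog1, of 19 genes within each pair of libraries with the same letter, at day 1 and at day 13 (circle, square and triangle for pairs a, b and c). At day 13 Mapt, Stmn2, Stmn4, Gap43 and Crmp1 lie below 0 in all 3 pairs and Ttyh1 and Cck above 0, with pair a nearest to 0 for most cytoskeleton genes.

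With the replicate block within day, 267 genes were higher and 440 lower with Neurog3 at day 13, and 2835 had an unadjusted p under 0.05. The genes below were chosen after their values were seen. Lower with Neurog3 were the axonal genes Cntn2 (-2.06 ± 0.14, adjusted p = 1.41e-05), Mapt (-1.50 ± 0.23), Stmn4 (-1.66 ± 0.30), Gap43 (-1.39 ± 0.23) and Stmn2 (-1.35 ± 0.25, adjusted p = 0.0103), the factors Neurod1 (-1.24 ± 0.23) and Neurod6 (-1.39 ± 0.28), and the receptor subunit Gria2 (-1.02 ± 0.24). Higher with Neurog3 were Ttyh1 (1.86 ± 0.13, adjusted p = 1.41e-05), Col9a1 (2.33 ± 0.17), albumin, Alb (2.44 ± 0.20), the peptide Cck (1.78 ± 0.20), the glial-family receptor Gfra3 (1.56 ± 0.17), Neurod2 (1.10 ± 0.28) and Heyl (1.37 ± 0.25). Of the cytoskeleton list 10 genes were lower and 0 higher, of the synapse list 4 and 0, of the muscle list 4 and 0, and of the proneural list 5 and 3. The cytoskeleton (adjusted p = 5.03e-15, and adjusted p = 0.625 with an estimated correlation), synapse (adjusted p = 7.67e-07, and adjusted p = 0.625 with an estimated correlation) and muscle lists (adjusted p = 3.8e-10, and adjusted p = 0.625 with an estimated correlation) were called lower in this fit too. So were channels (adjusted p = 8.23e-06, and adjusted p = 0.625 with an estimated correlation), sensory (adjusted p = 0.0247, and adjusted p = 0.625 with an estimated correlation) and cholesterol genes (adjusted p = 0.000104, and adjusted p = 0.625 with an estimated correlation). Interferon genes were called lower with the block (adjusted p = 0.00107, and adjusted p = 0.857 with an estimated correlation) and not without it. Without letter a, b or c the counts of higher and lower genes were 313 and 598, 47 and 45, and 135 and 230, and 528, 90 and 267 of the 707 genes were called again. Without letter c the synapse list was not called (median -0.22, adjusted p = 0.101).

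The interaction, asking whether the change from day 1 to day 13 differed between the factors, called 0 genes by edgeR's quasi-likelihood test. There were 471 genes with an unadjusted p under 0.05 where 844 would come by chance, and DESeq2 called 2. The pairing of the letters is left out here too, so the low count does not show equal changes under the factors. Camera called the cytoskeleton list (median -0.80; adjusted p = 9.78e-08, and adjusted p = 0.628 with an estimated correlation), the synapse list (-0.40; adjusted p = 0.000526, and adjusted p = 0.683 with an estimated correlation), skeletal muscle (-0.73; adjusted p = 0.00396, and adjusted p = 0.8 with an estimated correlation), cholesterol synthesis (-0.48; adjusted p = 2.18e-05, and adjusted p = 0.683 with an estimated correlation) and interferon response (-0.71; adjusted p = 0.00261, and adjusted p = 0.85 with an estimated correlation), all 5 with a smaller rise or larger fall under Neurog3. With the replicate block within day, 15 genes had a larger and 17 a smaller change under Neurog3. Chosen after their values were seen, Sct (2.08 ± 0.23, adjusted p = 0.0117) and Cck (2.35 ± 0.28) had positive differences, and Ccbe1 (-1.67 ± 0.20) and Cntn2 (-1.77 ± 0.28) negative ones.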

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

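The interaction test and the splits of the libraries were chosen before their results were seen, and the other tests in this part were chosen after.

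The change from day 1 to day 13 was tested for a difference between the factors, and 5 gene lists drew attention because that test called them. The median log2 difference, Neurog3 minus Neurog1, was -0.80 for neuronal cytoskeleton and RNA binding, -0.40 for synapse and vesicle release, -0.73 for skeletal muscle, -0.48 for cholesterol synthesis and -0.71 for interferon response. None of the 5 held when camera estimated the correlation within the list, with adjusted p from 0.628 to 0.85. With the replicate block within day, 32 genes differed between the factors in their change over time, among them Sct, Cck, Cntn2 and Ccbe1. Leaving out letter a, b or c from that fit gave 80, 1 and 11 genes. In the fit without the block edgeR called 0 genes (471 at an unadjusted p under 0.05) and DESeq2 2. With a real count of 0, 50 of 50 drawn splits give at least as many by construction, which says nothing about chance. The highest of the other splits called 38 genes, and the cause of that count was not tested.

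With a preset correlation, cytoskeleton and synapse genes were lower as lists with Neurog3 than with Neurog1 at day 13, and neither call held with an estimated correlation (adjusted p = 0.27 and 0.311). For the cytoskeleton list, the median lay below the central 95% of 10000 random lists matched on expression in 2 of the 3 pairs (-0.67 in b, -1.21 in c, not -0.07 in a). At the preset correlation it was called without any 1 letter (medians -0.88, -0.56 and -0.35 without a, b and c). The fall was thus not in 1 pair alone, but it was not in all 3. Random lists and the preset correlation allow for little or no correlation between these genes. They therefore cannot show that the difference exceeds the spread between libraries. Since scaling moves the random lists alike, these values argue against scaling of the libraries. For the synapse list, 2 of the 3 pairs also lay below (-0.33 and -0.93, not -0.01), but without letter c it was not called at day 13 (median -0.22, adjusted p = 0.101) or in the interaction (adjusted p = 0.211), so whether 1 pair of libraries makes that difference stays open. A smaller share of neurons in the cultures with Neurog3 cannot be told apart from a difference within neurons: among members at least 16-fold above the controls, the 9 cytoskeleton genes lay below the 19 proneural genes by -0.36 ± 0.09 (mean and SD of 3 pairs), but 9 of these 19 had already risen at day 1 under both factors and need not follow the share of neurons. The proneural genes themselves lay at -0.23 ± 0.46, and Mapt, Stmn2 and Stmn4 were called lower with Neurog3 in the fit with the replicate block within day, with the cause of that difference open.

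The interferon medians of the pairs at day 13 were -1.24, -0.72 and 0.33 for a, b and c, the cholesterol medians 0.01, -0.36 and -0.48, and the muscle medians -0.14, -1.66 and -1.22, and no explanation was tested for these 3 lists.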

How the results depend on the processing

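The replicate block within day, the robust option and leaving out 1 letter of every group were chosen after seeing the data. The counts for day 13 against the controls, and the higher counts for day 13 against day 1, stayed within 1.5 times their value under every alternative run. At an adjusted p under 0.01, a stricter threshold, day 1 against the controls gave 681 higher and 416 lower with Neurog1 and 683 and 437 with Neurog3, and 1 gene was called lower between the factors at day 13. A 2-fold minimum, also stricter, left 3001 lower for day 13 against day 1 with Neurog3, and 2664 and 2543 genes lower under both factors at day 13 against the controls and against day 1. Without a low-count filter the factors differed in 2 and 2 genes (higher and lower) at day 1 and in 32 and 61 at day 13. DESeq2's Wald test gave 2 and 2 at day 1, 30 and 56 at day 13, and 2 for the interaction. A fit of only the libraries of the groups compared gave 2 lower at day 1 and 1 lower at day 13. The cause was not tested for these 3 alternatives. Size factors, a mean CPM of at least 1, library totals and the robust option moved 0 of the counts by over 1.5 times.

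The replicate block over all libraries gave 1485 higher and 1275 lower for Neurog1 at day 1 against the controls. For Neurog3 it gave 1562 and 1324. Between the factors, the replicate block over all libraries gave 2 genes higher at day 13. The replicate block within day gave 9 and 18 at day 1, 267 and 440 at day 13, and 32 for the interaction. In its 87 list tests it added 6 calls and ended 0. The cause was not tested for either block. In libraries simulated in pairs the block found 82 of 100 genes raised or lowered 2-fold at day 13 against 14 without it, with 20 false calls among 200 against 0 among 77.

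Leaving out replicates, each library in turn or 1 letter of every group, uses fewer samples. For Neurog1 at day 1 it gave 584 to 975 higher and 360 to 789 lower, and for Neurog3 535 to 1085 and 351 to 825. Lower genes between the days with Neurog1 ranged from 3057 to 4465. The lower count for Neurog1 at day 1 was 578 without D1_Ngn1 replicate a and 563 without replicate b. Between the factors at day 13 the ranges were 1 to 2 higher (2 without D13_Ngn3 replicate a or b) and 1 to 5 lower (5 without D13_Ngn1 replicate a, 1 without D13_Ngn1 replicate b or D13_Ngn3 replicate a or c). C1qc at day 13 with Neurog3 against the controls (0.72, not called) ranged from -2.50 (without replicate a) to 1.37, with -2.31 without D13_Ngn3 replicate a. Lyz2 (1.53, not called) between the days with Neurog3 ranged from -1.18 (without replicate a) to 2.17.

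Of the 89 list calls over the 8 comparisons and the interaction, 5 held with an estimated correlation, where fry gave 95, the letter block 88 and library totals 84. The cause of the fall to 5 was not tested. Interferon response at day 13 had adjusted p from 0.0202 to 0.755 over its alternatives with Neurog1 and from 0.0526 to 0.786 with Neurog3. For the genes named, 649 called results had 12325 alternatives, of which 12325 had the same direction, 11715 were also called, and 0 reversed. Many of these genes were named for large folds in the same data. The 2-fold minimum and the adjusted p under 0.01 reuse the main fit's direction. The agreement in direction was therefore partly fixed in advance. Depth limits the folds: with 3 counts or fewer in both groups of a comparison no fold is given.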

Other observations

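The grouping of genes by their course over time and the tests on scaling, cell shares and medium, and the splits with the replicate block within day, were chosen after the results were seen, and the test on Xist and the other splits before.

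Some genes of the early response were lower by day 13. Of the genes that rose at day 1 under both factors, 301 were lower at day 13 than at day 1 under both, and 143 of these were not called against the controls at day 13. The genes named here were chosen after their values were seen. The pentraxin Nptx2 stood at 5.95 CPM in the controls, 108 and 113 at day 1 (Neurog1, Neurog3) and 5.67 and 9.23 at day 13, and the signalling gene Wnt10a at 0.816, 40.9 and 36.9, and 0.219 and 1.42 CPM. These 2 genes were not called against the controls at day 13, but 5 others stayed above the controls under both factors. Gal stood at 0.0623 CPM in the controls, 409 and 617 at day 1 and 3.2 and 1.89 at day 13. The axon guidance gene Sema7a stood at 1.44, 203 and 188, and 23.2 and 28.6 CPM, and the peptide-binding Crhbp at 0.465, 116 and 65.6, and 6.12 and 2.85. The substance P receptor Tacr1 (0.188 CPM in the controls, 3.1 and 2.19 at day 13) and the zinc finger repressor Gfi1 (0.0221, and 0.194 and 0.201) were the others. The Gfi1 levels rest on few counts, and no counting interval is given for them.

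The genes of the early response were followed to day 13, without a test between rises and falls. Of the 966 genes that rose at day 1 under both factors, 659 (68.2%) were higher than the controls at day 13 under both, 43 (4.45%) were lower and 169 (17.5%) were not called under either. Of the 730 that fell, 315 (43.2%) were lower at day 13, 108 (14.8%) were higher and 197 (27%) were not called under either. Over all 16872 genes tested, 4853 were higher and 4037 lower than the controls at day 13 under both factors. Map2 and the matrix gene Postn fell at day 1 and were higher than the controls at day 13 under both factors. Postn stood at 1757 CPM in the controls, 744 and 639.5 at day 1 and 3442 and 3238 at day 13. Aspn, a matrix proteoglycan, fell from 101 CPM in the controls to 2.02 and 2.18 at day 1 and stood at 288 and 223 at day 13, called higher than the controls with Neurog1 (adjusted p = 0.0309) and not with Neurog3 (adjusted p = 0.0934). Both days are set against the same control libraries, and the 301 genes above were chosen by 2 comparisons for each factor that share its day-1 libraries. In 20 simulations of unchanged groups at most 0 genes rose, and at most 0 fell, under both factors at day 1. That left no gene to follow, so these simulations do not test the 301 or the shares at day 13. What the shared libraries add among genes that did change at day 1 was not estimated.

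At day 13, 15 of 32 fibroblast and matrix genes were higher and 7 lower than in the controls under both factors, in a list that was not called, while 14 of 15 contractile genes were lower. The rises among the matrix genes beside the contractile falls were weighed. With library totals only, 13 of 15 contractile genes stayed lower and 16 matrix genes higher under both factors. That setting moved the median of all genes only from 0.10 to 0.40 with each factor, too little to test changes of this size. A scaling factor moves all genes of a library alike, so rises beside falls argue against scaling alone. Neurons replacing fibroblasts with no other change would lower matrix genes, and 15 of the 32 were higher. The medium and the days in culture cannot be told apart from the factors here, because 0 control libraries are labelled day 13.

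Transcripts of the Y chromosome were lowest in replicate a in 20 of 20 comparisons of a gene within a group. A hypothesis is that the letters mark separate fibroblast preparations with different shares of male embryos. Xist, expressed from the inactive X, was highest in replicate a in 4 of 5 groups. This goes with the hypothesis, and no other explanation was tested. Over all genes, however, libraries of the same letter were not alike in every comparison. Between day 13 and the controls their residuals correlated at -0.145, -0.0626 and -0.0328 with Neurog1 (a, b and c). With Neurog3 the values were -0.146, -0.0781 and -0.0709.

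The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For the controls against Neurog1 and Neurog3, the real counts were 2058 and 2156 at day 1 (highest other split 1 and 0) and 10016 and 9719 at day 13 (0 and 0), and in each 1 split, the real one, gave as many. Between the days the real counts were 9766 and 9410 (highest other 0 and 0, 1 split with as many in each). Between the factors at day 1 the real count was 2 (highest other 0, 1 split). Between the factors at day 13, 2 of the 10 splits gave as many as the real count of 4. The other one, which put Neurog1 replicates a and b with Neurog3 replicate a, called 28 genes. It parted only the libraries of letter b, and the cause of its count was not tested. With the replicate block within day only 4 splits part the 3 pairs, again too few, with real counts of 27 and 707 (highest other 0 and 0, 1 split each).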
